A study of Mus musculus with 9 samples.

How the data were processed

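RNA of 9 whole spinal cord samples from wild-type mice was sequenced, 3 each from naive mice, mice with experimental autoimmune encephalomyelitis (EAE) given vehicle, and mice with EAE given GV1001. Per the labels, RNA was extracted with TRIzol or with a Maxwell RSC kit, and which of these was used for which sample is not stated. Libraries were made with a QuantSeq 3′ mRNA kit, which reads the ends of transcripts. The deposited values are raw read counts per gene symbol. The authors named FastQC, STAR, HTSeq and the mouse build GRCm39, without versions or an annotation release. Whether molecular identifiers were used is not stated. The 9 files of single libraries held the same values as the table of all samples. No coordinates are given, since the annotation used here for checks belongs to an earlier build.

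Total counts per library ranged from 5247246 to 6174870. Of 40879 gene symbols, 14039 had no count in any library. A level below 3 counts in a library, 0.486 to 0.572 CPM (counts scaled to the library total), was treated as the floor. A fold against a group with no counts was computed against 3 counts over the group and is given as a lower bound. A ratio with 1 to 3 counts in a group has an exact Poisson interval at 95%. Floors and intervals cover counting error only.

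Groups were taken from the sample titles and the treatment labels. Genes were filtered with filterByExpr by group (minimum count 10), which left 15351, and normalised by TMM. Changes were tested with the edgeR 4.0.16 quasi-likelihood F test in a fit of all 9 libraries with 1 coefficient per group, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic. The current form of the quasi-likelihood fit was used, with the older form as an alternative. Both had been seen before this was settled. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run beside it, in R 4.3.3. On the data, limma-voom used the same 15351 genes. DESeq2 was run without this filter and gave a fold change for 26827 genes, so its counts cover another set of genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

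Before the data were examined, 41 gene lists were fixed for cell types of the cord, infiltrating cells, pathways, neighbouring tissues and RNA quality. The 39 with at least 5 tested members were tested two-sided with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists. The same test with an estimated correlation and limma's fry stand beside it. The list of natural killer cells had 1 tested member and that of adipocytes 4, so neither was tested. For the mitochondrially encoded list, 13 symbols were matched to the spelling in the table after it was seen, and 3 list symbols had no match. The score of a list in a library is the mean log2 CPM of its members relative to the naive mean. Scores were compared with a two-sided exact permutation test, which for 3 against 3 libraries has 20 assignments and a smallest p of 0.1. The lists mark transcripts in whole tissue and count no cells.

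The named genes were fixed by rule. In each comparison with EAE vehicle, they were the 8 largest changes per direction among genes past the threshold, at 5 CPM or more in a group and with no overlap between groups. Predicted symbols and immune receptor segments were left out. Up to 2 passing members and the most abundant member of each list were added, with 10 genes fixed in advance, among them Mbp, Mog, Gfap, Aif1, P2ry12, Tmem119, Cd74, Cd4 and Tert. Some genes that the rule names are not reported here. In GV1001 against naive they were the 3 largest per direction. Where fewer than 5 genes passed, the 10 with the smallest p were given as values that did not pass. Tert, the gene of the protein from which GV1001 derives, had 1, 3 and 7 counts in the naive, vehicle and GV1001 groups and was not tested. Its ratio was 3.07 in vehicle against naive (95% interval 0.247 to 161) and 2.25 in GV1001 against vehicle (0.514 to 13.5).

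Genes counted as moved back had to pass in EAE vehicle against naive and in GV1001 against EAE vehicle with opposite signs. Because both comparisons share the vehicle libraries, the correlation and covariance of fold changes were set beside 1000 simulations without a disease or treatment effect. Alternatives covered the tool, normalisation, filter, threshold, groups in the fit, the replicate number as a block, list tests, lists under a strict filter, lists without members shared between lists and leaving out each library. The labels do not say that replicate numbers pair samples across groups. Of the 9 same-number pairs of libraries, 2 had a correlation above 0.1 after group means were removed, so the block was kept as an alternative. For each pair of groups, the counts were repeated over the 10 splits of the 6 libraries into 3 and 3.

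The procedure was tested on counts simulated from the spread of these libraries, with 100 genes changed 2-fold, 100 changed 4-fold and a list of 20 more raised 2-fold. The changed genes were drawn at random above 5 CPM, with the same spread in all groups, and changed in vehicle against naive only. Recovery of genes that vary widely among diseased libraries, or between GV1001 and vehicle, was not tested. edgeR recovered 57% and 92% of the first 200 and 12 of the 20, with 5 false calls among 166. DESeq2 recovered 72%, 98% and 14 of the 20, with 26 false calls among 210, and limma-voom 53%, 91% and 12 of the 20, with 4 among 160. Of 200 random lists, 9 passed an unadjusted p of 0.05 in the list test. The simulated genes varied independently, so these lists held no correlation for the test to miss. In the data the estimated correlation was 0.941 for MHC class I and 0.294 for cholesterol synthesis genes. The 9 therefore do not show how often such lists pass by chance.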

Results

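Gene expression was measured in whole spinal cord from wild-type mice by 3′ mRNA sequencing. The 9 libraries fell into 3 groups of 3. Naive mice had no disease. The other groups had experimental autoimmune encephalomyelitis (EAE), a model of multiple sclerosis in which an immune response to myelin inflames the spinal cord, and received vehicle or GV1001, a peptide derived from telomerase. The labels do not say whether the 3 replicates of a group are separate animals. Total counts ranged from 5247246 to 6174870. They were 5612308, 5792583 and 5542411 in naive replicates 1 to 3, 5568907, 5247246 and 5736823 in the vehicle replicates, and 5292975, 5671814 and 6174870 in the GV1001 replicates. Of 40879 gene symbols, 15351 had enough counts to be tested. A count of 0 in a library allowed a level of up to 0.486 to 0.572 CPM (counts scaled to the library total), and this floor covers counting error only.

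The diseased libraries differed widely within their groups. The median standard deviation (SD) of a gene's log2 CPM was 0.163 in naive, 0.264 in vehicle and 0.216 in GV1001 libraries. The first principal component held 46.2% of the variance. Naive libraries lay at −41.3, −28.7 and −36.6 on it, vehicle libraries at 80.4, −7 and 27, and GV1001 libraries at −24, 34.9 and −4.7. Markers of neighbouring tissues also took different shares of the libraries. The skeletal muscle list, without Pvalb, which cord neurons also express, took 0.0041%, 0.00492% and 0.0279% of counts in the naive libraries, 0.0154%, 0.0595% and 0.00387% in the vehicle libraries, and 0.498%, 0.131% and 0.0464% in the GV1001 libraries. The Schwann cell list, which marks nerve roots, took 0.141%, 0.091% and 0.141% in naive, 0.048%, 0.154% and 0.242% in vehicle, and 0.235%, 0.25% and 0.345% in GV1001 libraries. Hemoglobin transcripts took 0.482% of vehicle replicate 2 and between 0.025% and 0.071% of the other libraries.

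The comparison of vehicle-treated EAE with naive cord asked which transcripts differ in the diseased cord. Atf3, a transcription factor induced by cell stress and nerve injury, rose from 0.898 ± 0.162 to 13.9 ± 5.17 CPM (SD, n = 3). Lrg1, a glycoprotein made by activated endothelium, rose from 6.79 ± 1.64 to 48.9 ± 13.9 CPM, and the chemokine Ccl12 from 1.14 ± 0.238 to 22.7 ± 4.31 CPM. The log2 fold changes were 3.92 ± 0.47 (SE), 2.84 ± 0.34 and 4.28 ± 0.51, each with an adjusted p of 0.0258. These calls were lost in limma-voom, with the replicate number as a block, and when any naive library was left out. Gene lists of antigen presentation, microglia, infiltrating leukocytes and reactive astrocytes were higher in all 3 vehicle libraries than in any naive library, and lists of cholesterol synthesis, myelin and neurons were lower. With an estimated correlation 0 lists passed, with a smallest adjusted p of 0.257.

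Genes of antigen presentation by MHC class II had the largest score difference of the 39 lists tested. The score, the mean log2 CPM of a list's members, was higher by 3.31 (SD 1.84 in vehicle and 0.23 in naive, n = 3), and 13 of 13 tested members were higher when adjusted over the list alone. Cd74, the invariant chain of class II, was at 280 CPM in vehicle and 6.37 in naive libraries, with 724, 26.3 and 89.5 CPM in the 3 vehicle replicates. Its log2 fold change was 5.44 ± 1.35, with an adjusted p of 0.0772 over all genes. The protease Ctss was at 1370 against 101 CPM (3.76 ± 0.83). The class I list differed by 1.92, with 12 of 13 members higher over the list alone and B2m at 2010 against 285 CPM (2.82 ± 0.87). Histocompatibility genes have near-identical copies, so the split of reads among them is uncertain. The interferon gamma list differed by 2.71 (13 of 15 members higher, adjusted over the list alone), with the GTPase Iigp1 at 4.61 ± 1.31. The type I interferon list differed by 1.80 (20 of 24). Without vehicle replicate 1 the log2 fold changes were 3.18 for Cd74, 2.56 for Ctss, 1.27 for B2m and 2.54 for Iigp1. The MHC class II, class I, interferon gamma and type I interferon lists then differed by 2.3, 1.17, 1.73 and 1.14. The adjusted p was 0.257 with an estimated correlation for each of these lists.

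Microglial and phagocyte genes differed in the same direction. The list of disease-associated microglia and phagocytes was higher by 2.38, with 22 of 24 members higher when adjusted over the list alone, although its most abundant member, the ferritin chain Fth1, differed by only 0.15 ± 0.13. The homeostatic microglia list was higher by 1.09 (11 of 17 members). Among its members, the fractalkine receptor Cx3cr1 was at 1.83 ± 0.50, Tmem119 at 1.68 ± 0.42 and the purinergic receptor P2ry12 at 0.52 ± 0.26. The pan-microglial gene Aif1 was at 74.1 against 8.32 CPM (3.15 ± 0.81). Complement genes differed by 2.33 (16 of 18), with C1qa at 557 against 58.4 CPM (3.25 ± 0.75), and inflammasome and NF-kB genes by 1.65 (19 of 21), with Nfkbia at 1.18 ± 0.33. Without vehicle replicate 1 the log2 fold changes were 1.16 for Cx3cr1, 1.28 for Tmem119, 0.25 for P2ry12, 2.1 for Aif1, 2.28 for C1qa and 0.59 for Nfkbia. For each of these lists the adjusted p was 0.257 with an estimated correlation.

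Lists of infiltrating cells were also higher, by 2.21 for monocytes and macrophages, 1.48 for neutrophils, 2.06 for T cells, 2.39 for B and plasma cells and 0.97 for dendritic cells. Adjusted over the list alone, 14 of 18, 4 of 11, 5 of 7, 4 of 6 and 3 of 7 of their tested members were higher. The lists hold 24, 16, 22, 15 and 12 genes, and the members not tested give no evidence for these cells. A gene with counts in diseased libraries alone can pass the filter. The macrophage lysozyme Lyz2 was at 195 against 4.06 CPM (5.57 ± 1.21), S100a9 at 0.77 ± 0.49, Icos at 1.82 ± 0.72 and Ighm at 0.26 ± 0.26. Cd4 had no count in the naive libraries and 6.11, 0.572 and 0.349 CPM in the vehicle libraries, at least 13-fold higher against a floor of 0.177 CPM over the naive group. Chemokines differed by 2.37 (15 of 22), although their most abundant member, Cx3cl1, was at 150 against 172 CPM (−0.20 ± 0.11). T helper and inflammatory cytokines differed by 1.65 (2 of the 5 tested members, of 25 listed). Ccl5 was at 260, 10.9 and 8.81 CPM in the vehicle libraries and at 0.483 CPM in naive cord (7.53 ± 2.12). Without vehicle replicate 1 the log2 fold changes were 4.29 for Ccl5, 4.08 for Lyz2 and 0.62 for Icos. The monocyte, neutrophil, T cell, B and plasma cell and dendritic cell lists then differed by 1.41, 1.28, 1.19, 1.72 and 0.61. Chemokines differed by 1.75 and cytokines by 1.18. The adjusted p was again 0.257 with an estimated correlation for every list of this paragraph.

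Reactive astrocyte genes were higher by 1.93 (23 of 27 members, adjusted over the list alone), with the intermediate filament Gfap at 1240 against 676 CPM (0.88 ± 0.35). Genes of activated endothelium were higher by 1.35 (9 of 15), of proliferation by 1.08 (8 of 17) and of the immediate early response by 0.51 (5 higher and 1 lower of 14). The most abundant proliferation gene, Stmn1, was at 46.6 against 60 CPM (−0.37 ± 0.23). These lists had an adjusted p of 0.257 with an estimated correlation. Without vehicle replicate 1 the reactive astrocyte, activated endothelium, proliferation and immediate early lists differed by 1.55, 0.99, 0.64 and 0.41. The NRF2 antioxidant list was higher by 0.45 (4 higher and 1 lower of 15), with the metallothionein Mt2 at 3430 against 1160 CPM (1.56 ± 0.22) and an adjusted p of 0.355 with an estimated correlation.

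Enzymes of cholesterol synthesis, which oligodendrocytes need for myelin, were lower by −0.47 (SD 0.22 in vehicle and 0.09 in naive), with 22 of 23 members negative and 16 lower when adjusted over the list alone. Hmgcs1, an early enzyme of the pathway, was at 377 against 578 CPM (−0.62 ± 0.18). Myelin genes were lower by −0.16, with 23 of 29 members negative and 2 lower and 1 higher over the list alone. Mbp was at 7820 against 9750 CPM (−0.32 ± 0.15) and Mog at −0.26 ± 0.12, and without vehicle replicate 1 these were −0.20 and −0.17. The neuron list was lower by −0.32 (9 of 24 members), with the neurofilament Nefl at −0.34 ± 0.11. The motor neuron list was lower by −0.54 (0 of 10) and mitochondrially encoded transcripts by −0.36 (2 of 9). The adjusted p was 0.257 with an estimated correlation for each. The dorsal root ganglion list was lower by −1.29 (0 of 10), with an adjusted p of 0.537 with an estimated correlation, and it varied with an SD of 2.08 among the naive libraries. The general astrocyte, oligodendrocyte precursor and endothelial lists did not pass, with score differences of 0.02, 0.08 and −0.01, and neither did the Schwann cell and skeletal muscle lists, at 0.09 and 0.67.

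edgeR called 3 of 15351 genes, all higher, with 2970 genes at an unadjusted p under 0.05 where chance gives 768. DESeq2, run without the filter, called 1084 genes, 821 higher and 263 lower, and 3 of these were the edgeR calls. Of the 1084, 1032 were among the genes tested in edgeR. limma-voom called 0, with a smallest adjusted p of 0.0869 and 2671 genes at an unadjusted p under 0.05. Vehicle and naive libraries did not overlap for 23.8% of genes, where chance gives 10%. The 7 other genes among the 10 smallest p had an adjusted p of 0.0629. They were Cacng7 (−1.27 ± 0.19), Lypd1 (−0.71 ± 0.11), Mt2, Fcrl2 (1.86 ± 0.29), the ribosomal protein genes Rps16 (0.83 ± 0.12) and Rpl28 (0.91 ± 0.14), which have many near-identical copies, and Cd244a. Cd244a had 39 against 3 counts, a ratio of 13.3 with a 95% exact Poisson interval of 4.23 to 67.3. Of 39 lists, 26 passed, 20 higher and 6 lower, and 0 did with an estimated correlation. The edgeR count was 0 without each naive replicate in turn or without GV1001 replicate 3, 1 without vehicle replicate 3, 5 without vehicle replicate 1, 81 without GV1001 replicate 1 and 1652 without vehicle replicate 2. The motor neuron and NRF2 lists did not pass without vehicle replicate 1, nor the dorsal root ganglion list without naive replicate 2 or with muscle and Schwann scores as covariates.

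**Figure D1:**
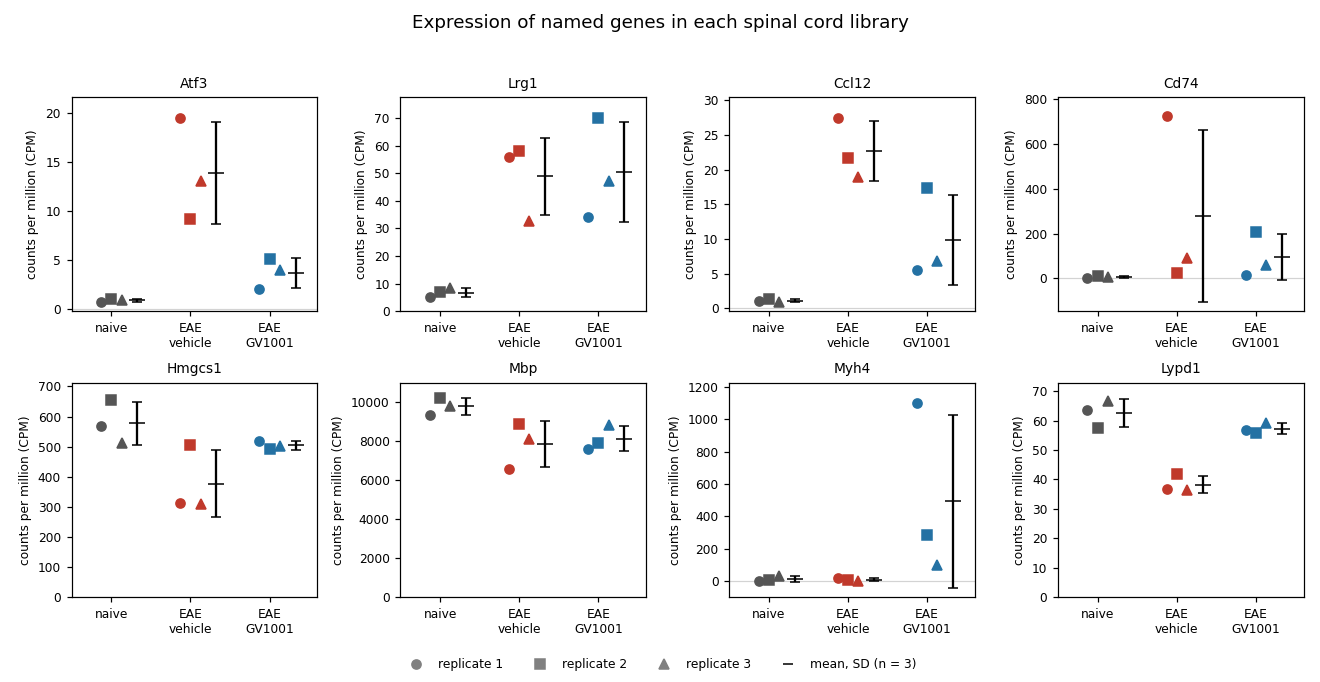
Level of 8 named genes in CPM (vertical axis, linear, 1 panel per gene) in naive, EAE vehicle and EAE GV1001 libraries. Points are libraries with the marker giving the replicate, and bars are the mean and SD of n = 3, which reach below 0 for Cd74 and Myh4. Atf3, Lrg1 and Ccl12 were higher in each vehicle library than in each naive library, Cd74 was at 724 CPM in vehicle replicate 1 alone, and Myh4 was at 1100 CPM in GV1001 replicate 1.

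The comparison of GV1001 with vehicle, both in EAE, asked what differs in the cord of diseased mice given the peptide. On average the lists of microglia, antigen presentation and reactive astrocytes were lower with GV1001, and cholesterol synthesis genes were higher. With an estimated correlation 0 lists passed, with a smallest adjusted p of 0.504. The immune differences were not separated from muscle and nerve root markers, as given below. The libraries overlapped for most lists, and only cholesterol synthesis, motor neuron and B and plasma cell genes separated all 3 GV1001 from all 3 vehicle libraries. These were 3 of 39 lists, where chance gives 10%, so the separation does not set these lists apart. Atf3 was at 3.74 ± 1.52 CPM with GV1001 and 13.9 ± 5.17 with vehicle (SD, n = 3), a log2 fold change of −1.87 ± 0.35. Lypd1 was at 57.3 ± 1.79 against 38.3 ± 2.98 CPM (0.58 ± 0.11). Neither passed in edgeR, with an adjusted p of 0.528, and both passed in DESeq2, with an adjusted p of 0.028 and 0.0483.

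Cholesterol synthesis genes were higher with GV1001 by 0.36 (SD 0.07 in GV1001 and 0.22 in vehicle), with 22 of 23 members positive and 2 higher when adjusted over the list alone. The adjusted p was 4.07e-08, and 0.504 with an estimated correlation. Hmgcs1 was at 504 against 377 CPM (0.42 ± 0.18). Leaving out any single library kept this list past the threshold, with differences from 0.24 to 0.44. The Schwann cell list, whose cells also make myelin lipids, was higher in the same libraries by 1.04. Myelin genes did not pass, with a score difference of −0.01, a median fold change of 0.01 and a test direction of down. Mbp was at 8090 against 7820 CPM (0.05 ± 0.15) and Mog at 0.08 ± 0.12.

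Genes of disease-associated microglia and phagocytes were lower with GV1001 by −1.29 (SD 0.96 in GV1001 and 1.48 in vehicle), with 23 of 24 members negative and 15 lower when adjusted over the list alone. The homeostatic microglia list was lower by −0.66 (3 of 17 members), B and plasma cell genes by −1.61 (2 of 6), and reactive astrocyte genes by −0.88 (0 of 27), each with an adjusted p of 0.504 with an estimated correlation. The MHC class II, class I, interferon gamma, type I interferon, complement and inflammasome lists were lower by −1.07, −0.85, −1.11, −0.72, −0.82 and −0.74, with an adjusted p of 0.567 with an estimated correlation. Without vehicle replicate 1 these differences were −0.06, −0.1, −0.14, −0.05, −0.25 and −0.15. Among all members of these 6 lists, 1 was lower when adjusted over the list alone. Cd74 was at 14.6, 210 and 61.3 CPM in the GV1001 replicates (−1.55 ± 1.03, and 0.71 without vehicle replicate 1), C1qa at 179 against 557 CPM (−1.64 ± 0.70), Aif1 at −1.63 ± 0.70, Tmem119 at −0.77 ± 0.39 and Gfap at −0.59 ± 0.34. Without vehicle replicate 1 these were −0.66 for C1qa, −0.58 for Aif1, −0.37 for Tmem119 and −0.34 for Gfap. Dendritic cell, cytokine and proliferation genes were lower by −0.60, −0.90 and −0.63 with 0.504, and chemokines by −0.71 with 0.572, as the adjusted p with an estimated correlation, although Stmn1 was at 0.14 ± 0.23 and Cx3cl1 at 0.16 ± 0.11. The monocyte, neutrophil and T cell lists did not pass, at −0.53, 0.28 and −0.71. With muscle and Schwann scores as covariates, the MHC class II, class I, both interferon, complement and inflammasome lists passed in the opposite direction, and both microglia, B and plasma cell, reactive astrocyte, dendritic cell, cytokine, chemokine and proliferation lists did not pass. These passes used the preset correlation only. The mean immune score then differed by 0.87 (SE 1.02), so no rise with GV1001 was shown. Vehicle replicate 1 had both the lowest Schwann score, −0.94, and the highest immune score, 3.27. Muscle and nerve root transcripts took a larger share of the GV1001 libraries on average, with overlap between the groups.

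Markers of neighbouring tissues were higher with GV1001 on average. The skeletal muscle list was higher by 2.69 (11 of 14 members, adjusted over the list alone), with the fast myosin Myh4 at 1100, 283 and 97.5 CPM in the GV1001 replicates and 17.4, 8.83 and 1.19 CPM in the vehicle replicates. The muscle score of vehicle replicate 2, at 2.41, lay above that of GV1001 replicate 3, at 1.72. The Schwann cell list was higher by 1.04 (4 of 13). The dorsal root ganglion list was higher by 1.98 (0 of 10), with Calca at 1.33 ± 0.56. Each had an adjusted p of 0.504 with an estimated correlation. Neuron genes were higher by 0.18 (0 of 24, with 0.567), motor neuron genes by 0.52 (0 of 10, with 0.504), endothelial genes by 0.17 (0 of 18, with 0.504) and meningeal fibroblast genes by 0.56 (0 of 18, with 0.567), as the adjusted p with an estimated correlation. Mitochondrially encoded and nuclear respiratory chain genes were higher by 0.18 and 0.09 (with 0.504 and 0.654), and ependymal genes were lower by −0.34 (with 0.504).

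edgeR called 0 of 15351 genes between GV1001 and vehicle, with a smallest adjusted p of 0.528 and 1394 genes at an unadjusted p under 0.05 where chance gives 768. limma-voom called 0, with 1215 at an unadjusted p under 0.05. DESeq2 called 13, 10 higher and 3 lower. The 10 higher calls were the muscle genes Myh4, Mybpc2, Jsrp1 and Casq1, Pygm and Tpm1, which muscle also expresses, the dorsal root ganglion channel Scn11a, and Cdk5r2, Dact2 and Lypd1. Most of them thus mark neighbouring tissues. Casq1, Pygm and Tpm1 were named after their values were seen. The 10 smallest p in edgeR belonged to Atf3, Lypd1, Myh4, the muscle genes Mybpc2 (4.08 ± 0.73) and Jsrp1 (3.51 ± 0.61), and Cdk5r2 (0.54 ± 0.11), Dact2 (1.18 ± 0.24), Ntpcr (−0.68 ± 0.14), Spire2 (0.82 ± 0.17) and Tinagl1 (1.00 ± 0.20). The groups did not overlap for 10.5% of genes, where chance gives 10%. Of the 39 lists, 25 passed, 10 higher and 15 lower, and 0 did with an estimated correlation. Without vehicle replicate 1, 11 lists passed, and the MHC class II difference was −0.06. The 10 of the 25 that kept their call were the cholesterol, both microglia, B and plasma cell, reactive astrocyte, meningeal, Schwann cell, dorsal root ganglion, muscle and mitochondrially encoded lists. Their differences there were −0.65 for disease-associated and −0.27 for homeostatic microglia, −0.95 for B and plasma cells, −0.50 for reactive astrocytes and 0.52 for Schwann cells. The meningeal call was lost without vehicle replicate 2, and the mitochondrially encoded, respiratory chain and ependymal calls without vehicle replicate 3. The cytokine call was also lost without naive replicate 1, naive replicate 3, vehicle replicate 2 or GV1001 replicate 3, and the chemokine call without GV1001 replicate 3. Without GV1001 replicate 1, 13 lists passed. The 12 that lost their call were the dendritic cell, cytokine, chemokine, MHC class II and class I, both interferon, complement, inflammasome, ependymal, mitochondrially encoded and respiratory chain lists. With muscle and Schwann scores as covariates, and the preset correlation, 14 passed. Of the 25 lists, 3 kept their direction (cholesterol, meningeal and dorsal root ganglion) and 7 passed in the opposite direction (6 immune lists named above and the respiratory chain). The other 15 did not pass. These include the muscle and Schwann cell lists, whose group difference the covariates remove by construction, being their own scores. Without vehicle replicate 2, edgeR called 8 genes lower, all of which had been higher in vehicle than in naive cord by the same fit. They were A630001G21Rik, Abca1, Apoe, Gpnmb, Lpl, Ms4a7, Sirpa and Spp1, named after their values were seen. Vehicle replicate 2 had the lowest disease-associated microglia score of the vehicle libraries, 0.76 against 3.66 and 2.72. Leaving it out raises the vehicle mean of such genes in both comparisons, apart from any effect of GV1001. Without GV1001 replicate 3 edgeR called 1 gene, higher.

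**Figure D2:**
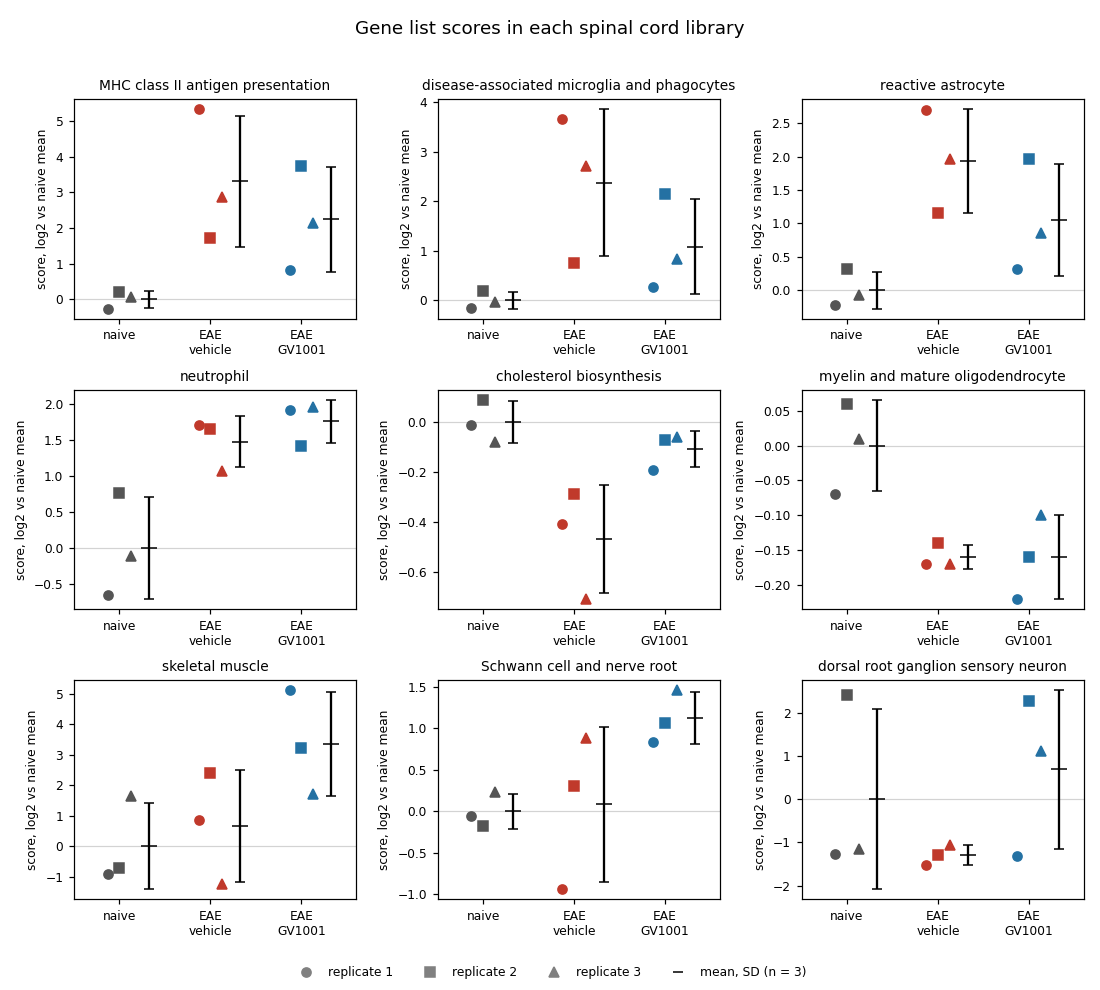
Scores of 9 gene lists (vertical axis, mean log2 CPM of the members relative to the naive mean, 1 panel per list) in naive, EAE vehicle and EAE GV1001 libraries. Points are libraries with the marker giving the replicate, and bars are the mean and SD of n = 3. Immune lists spread widely within both diseased groups, cholesterol synthesis scores of the GV1001 libraries lay above those of the vehicle libraries, and muscle scores were higher on average in the GV1001 libraries.

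The comparison of GV1001 with naive cord asked what still differs from the healthy cord in treated mice. Lrg1 was at 50.4 ± 18.2 against 6.79 ± 1.64 CPM (SD, n = 3), a log2 fold change of 2.89 ± 0.34 with an adjusted p of 0.061, and Ccl12 was at 9.88 against 1.14 CPM (3.09 ± 0.58). The other genes among the 10 smallest p were Ifitm1 (2.49 ± 0.40), the von Willebrand factor gene Vwf (1.45 ± 0.26), Egr2 (1.57 ± 0.30), Ahnak (0.91 ± 0.15), Ackr1 (0.69 ± 0.11), Xbp1 (0.62 ± 0.11), Cerox1 (−0.76 ± 0.13) and Cd244a, with 27 against 3 counts (ratio 8.90, 95% interval 2.74 to 45.8). The neutrophil list was higher by 1.76, with 8 of 11 members higher when adjusted over the list alone and an adjusted p of 0.279 with an estimated correlation. MHC class II was higher by 2.24 (4 of 13, with 0.377), complement by 1.51 (3 of 18, with 0.354), reactive astrocyte genes by 1.05 (5 of 27, with 0.404) and disease-associated microglia by 1.09 (0 of 24, with 0.524). Replicate 2 of GV1001 weighed most, as the replicates scored 0.32, 1.97 and 0.86 for reactive astrocyte genes. For disease-associated microglia they scored 0.28, 2.15 and 0.83. Skeletal muscle and Schwann cell genes were higher by 3.36 (12 of 14) and 1.12 (7 of 13), both with 0.343. Myelin genes were lower by −0.16 (1 of 29, with 0.279), neuron genes by −0.14 (0 of 24, with 0.525) and cholesterol synthesis genes by −0.11 (0 of 23, with 0.536). The values after "with" are the adjusted p with an estimated correlation.

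edgeR called 0 genes between GV1001 and naive, with 1121 at an unadjusted p under 0.05. limma-voom called 0, with 957, and DESeq2 called 46, 42 higher and 4 lower. Of the 46, 42 were among the genes tested in edgeR. The higher calls included the muscle genes Myh4, Mybpc2, Mylpf, Myom2, Casq1, Actc1, Ampd1 and Mylk2, beside Lrg1, Ccl12 and Vwf. The muscle genes other than Myh4 and Mybpc2 were named after their values were seen. The groups did not overlap for 17.1% of genes, where chance gives 10%. Of the 39 lists, 25 passed, 21 higher and 4 lower, and 0 did with an estimated correlation. The edgeR count was 3 without vehicle replicate 1, 2 without vehicle replicate 2, and 1 without vehicle replicate 3, GV1001 replicate 1 or GV1001 replicate 3. The cholesterol list did not pass without naive replicate 2 or GV1001 replicate 1. With muscle and Schwann scores as covariates, the cholesterol and endothelial lists did not pass. The Schwann cell and muscle lists did not pass there either, which was fixed in advance, since the covariates are their own scores. Without GV1001 replicate 2 the homeostatic microglia, T cell, MHC class I, proliferation, mitochondrially encoded and NRF2 lists lost their call.

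The last comparison asked whether genes changed in EAE were moved back with GV1001. By edgeR, 0 genes changed in EAE and then changed in the opposite direction with GV1001, since 0 passed in the second comparison, and limma-voom also gave 0. DESeq2 gave 7, where 0.35 would be expected if the calls were independent, which they are not, because both comparisons share the vehicle libraries. Atf3, Lpl and Tent5c were higher in EAE and lower with GV1001, and Cdk5r2, Dact2, Lypd1 and Scn11a the reverse. Of these, Lpl, Tent5c and Scn11a were named after their values were seen. Scn11a, a sodium channel of dorsal root ganglion neurons, had no count in the vehicle libraries, 0, 30 and 10 CPM in the GV1001 libraries and 0, 38.7 and 0 CPM in the naive libraries. It was at least 74-fold higher with GV1001 against a floor of 0.181 CPM over the vehicle group. Across genes, which are not independent replicates, the fold changes of the comparisons correlated at −0.672. Simulations with neither a disease nor a treatment effect, and the same spread in all groups, gave a median of −0.535. Their 95% range was −0.941 to 0.486, and the covariance of −0.167 also lay within its simulated range of −0.232 to 0.035. They do not show what a disease effect without a treatment effect would give. The spread of the 3 vehicle libraries alone would give a covariance of −0.084. Without vehicle replicate 2, the vehicle library with the lowest immune score, the edgeR count was 8. Leaving that library out raises the vehicle mean of immune genes, which both comparisons share, so the 8 do not show a reversal by GV1001.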

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

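The DESeq2 fits without single libraries, the muscle and Schwann covariates and the robust fit were chosen after seeing the data. The other alternatives were planned. Unless a sentence says otherwise, the cause of a difference was not tested.

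The 3 genes called between vehicle and naive stayed at 3 with the older quasi-likelihood fit, RLE or upper quartile factors, the strict filter (5 CPM in 3 libraries), without mitochondrial and hemoglobin genes, and with a 1.5-fold minimum. The count was 2 with those groups alone, 0 with limma-voom, the replicate block, the muscle covariate or an adjusted p under 0.01, 20 with library size only, 43 with the robust fit, 543 with no filter and 1084 with DESeq2. Leaving out a library gave 0 to 1652, and DESeq2 gave 404, 1799 and 1121 without vehicle replicate 1, vehicle replicate 2 and GV1001 replicate 1. Between GV1001 and vehicle, DESeq2 gave 13, and 18, 340 and 81 without the same libraries. Leaving out a library gave 0 to 8 in edgeR, and all other alternatives gave 0. Between GV1001 and naive, DESeq2 gave 46, and 182, 131 and 42. The older fit, upper quartile factors, library size only and no filter each gave 1, those groups alone gave 5, leaving out a library gave 0 to 3, and the others 0. Genes moved back were 7 with DESeq2, 0 to 8 leaving out a library and 0 otherwise.

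The lists called were 0 in each comparison with an estimated correlation, and 1, 0 and 0 with fry in vehicle against naive, GV1001 against vehicle and GV1001 against naive. Leaving out a library gave 26 to 29, 11 to 30 and 20 to 28, and the block 26, 25 and 24. With the covariates the count in GV1001 against vehicle was 14. The strict filter gave 24, 22 and 23, and members of 1 list only gave 25, 23 and 25. Under the strict filter T cell, B and plasma cell and cytokine lists in vehicle against naive, B and plasma cell and cytokine lists in GV1001 against vehicle, and T cells in GV1001 against naive had fewer than 5 members and were not tested, while ependymal in GV1001 against vehicle and NRF2 in GV1001 against naive did not pass. With members of 1 list only cytokines were not tested and chemokines did not pass in GV1001 against vehicle. Score differences moved by more than 1 SD in 27 cases, 25 of them with the median of members in place of their mean and 2 with a prior count of 0.5. With the smaller prior count, cytokines were at 2.27 in vehicle against naive and B and plasma cells at 1.27 in GV1001 against naive. With the median, differences in vehicle against naive were −0.10 for myelin, −0.20 for cholesterol synthesis, 3.25 for B and plasma cells, 1.02 for cytokines, −0.15 for general astrocytes, 0.67 for heat shock, 0.05 for NRF2, −0.11 for trophic factors and 0.18 for telomerase and GnRH genes. In GV1001 against vehicle they were −0.07 for myelin, 0.17 for cholesterol synthesis, 0.75 for neutrophils, 0.01 for pericytes, −0.55 for ependymal, −0.19 for heat shock and 0.04 for telomerase and GnRH genes. In GV1001 against naive they were −0.16 for oligodendrocyte precursors, 1.40 for B and plasma cells, −0.22 for general astrocytes, 0.06 for pericytes, −0.08 for mitochondrially encoded genes, 0.48 for heat shock, −0.01 for NRF2, −0.24 for trophic factors and 0.22 for telomerase and GnRH genes. A median over members at very different levels follows those near the middle, by construction.

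Some fold changes that had not passed changed sign, and their lowest and highest values leaving out a library follow. In vehicle against naive these were Atp5a1 (−0.05 to 0.26), Car3 (−0.96 to 1.33) and Hbb-bs (−0.35 to 2.16). In GV1001 against vehicle, immune genes ran from −2.29 to 0.34 for B2m, −3.76 to 1.74 for Ccl5, −2.86 to 0.71 for Cd74, −3.64 to 0.63 for Iigp1, −3.06 to 0.24 for Il1b, −1.46 to 0.38 for Icos, −0.54 to 0.01 for Ighm, −0.51 to 0.35 for Nfkbia and −0.30 to 0.01 for Fscn1. The others were Atp5a1 (−0.17 to 0.13), Chodl (−0.09 to 0.33), Hbb-bs (−2.28 to 0.22), Hsp90aa1 (−0.11 to 0.08), Mbp (−0.06 to 0.14), Mog (−0.01 to 0.22), Stmn1 (−0.01 to 0.46) and S100b (−0.08 to 0.08), which was 0 in limma-voom, with upper quartile factors, with no filter and with the block. The respiratory chain list, which had passed in GV1001 against vehicle, ran from −0.01 to 0.18. Depth limits genes near the floor, such as Tert and Cd4, which were not tested.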

Other observations

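The tests on immune, muscle and cholesterol genes were chosen after the result was seen, and so was the group of ribosomal protein genes. The counts over splits were planned.

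Of 82 cytoplasmic ribosomal protein genes, grouped after Rps16 and Rpl28 were seen among the smallest p, 80 were higher in vehicle than in naive cord. Their median log2 fold change was 0.51, 58 were higher and 1 lower when adjusted over the list alone, and p was 0.0535 with an estimated correlation. In GV1001 against vehicle 79 of the 82 were negative, with a median of −0.28 and a p of 0.117 with an estimated correlation. Scores were 0.74, 0.33 and 0.39 in the vehicle and 0.33, 0.27 and 0.11 in the GV1001 libraries. These genes have many near-identical copies, so their reads are hard to assign.

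Over the 15 immune lists fixed beforehand with at least 5 tested members, GV1001 libraries scored −0.8 relative to vehicle (SE 0.83), with 0.45, 2.2 and 1.01 in the GV1001 and 3.27, 1.09 and 1.7 in the vehicle replicates. Dilution by muscle or nerve root RNA would lower other cord transcripts alike, but with counts scaled to the library total alone 4 cord lists (astrocyte, oligodendrocyte precursor, myelin and endothelium) differed by −0.01 (SE 0.06) and the immune lists by −0.81 (SE 0.82), which argues against dilution as the whole cause. The gap between cord and immune scores was 0.8 (SE 0.81), which would leave dilution undecided, and the bound used was chosen after these values were seen. The immune difference was −0.5 (SE 0.93) with the muscle score as a covariate, 0.05 (SE 0.82) with the Schwann score and 0.87 (SE 1.02) with both. With both, of the 25 lists called 3 kept their direction, 7 passed in the opposite direction and 15 did not pass. The muscle and Schwann cell lists are among the 15 by construction, since the covariates are their own scores. The immune difference was thus not separated from these scores. It was −0.18 (SE 0.6) without vehicle replicate 1 and −0.42 (SE 0.88) without GV1001 replicate 1, so either library may carry it, and a difference in severity unrelated to treatment (exact permutation p = 0.4, smallest possible 0.1) or an effect of GV1001, not tested apart from it, also stays open.

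Skeletal muscle genes were higher on average in the GV1001 than in the vehicle libraries (adjusted p 0.504 with an estimated correlation), but vehicle replicate 2, at a score of 2.41, lay above GV1001 replicate 3, at 1.72. A candidate explanation is muscle carried along in dissection. The share of counts in the muscle list, leaving out Pvalb, which cord neurons also express, differed 6.8-fold between the highest and lowest naive library, without any treatment. That rested on naive replicate 3, at 0.0279% against 0.0041% and 0.00492%. Shares in the vehicle libraries were 0.0154%, 0.0595% and 0.00387%. The spread within groups goes with that explanation, but all 3 GV1001 libraries lay above the 3 naive libraries. A response of muscle genes to treatment was not tested and stays open.

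Cholesterol synthesis genes were higher with GV1001 than with vehicle by 0.36 (adjusted p 0.504 with an estimated correlation). The difference was 0.17 with the median level of members in each library, which follows members at middle levels. The median of the members' log2 fold changes was 0.419. If nerve root RNA were the cause, the difference should shrink with the Schwann score as a covariate, and it was 0.47 (SE 0.15), which argues against it as the whole cause. If RNA of inflammatory cells diluted the vehicle libraries, other cord lists should be higher by as much, and the neuron and motor neuron lists were higher by 0.18 and 0.52 while the myelin list differed by −0.01. The cholesterol score minus the cord score differed by 0.37 with the 4 cord lists above, 0.25 with both neuron lists added and 0.3 with pericyte and ependymal lists as well (SE 0.14 each), so the outcome depended on the lists taken and dilution stays open. A treatment effect stays open as a hypothesis, and so does a difference in severity unrelated to treatment. The exact permutation p of the cholesterol score was 0.1, the smallest possible, so that test cannot decide between them. In replicate order, vehicle libraries had immune scores of 3.27, 1.09 and 1.7 and cholesterol scores of −0.41, −0.29 and −0.71. The GV1001 libraries had immune scores of 0.45, 2.2 and 1.01 and cholesterol scores of −0.19, −0.07 and −0.06.

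Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. The genes called by edgeR were 3 in vehicle against naive and at most 0 in the other splits, so 1 split of the 10 gave as many. In GV1001 against vehicle they were 0, against up to 637, and in GV1001 against naive 0, against up to 15, so that all 10 splits gave as many. For DESeq2 the real and highest other counts were 1084 and 61, 13 and 1077, and 46 and 47, with 1, 4 and 2 splits as large. For lists they were 26 and 25, 25 and 29, and 25 and 21, with 1, 2 and 1 splits as large. For genes moved back they were 0 and 563, with 10 splits as large. The split with 637 set vehicle replicates 1 and 3 and GV1001 replicate 2, the 3 diseased libraries with the highest immune scores, against the others. It points to a structure of the diseased samples that does not follow the treatment labels.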
